A study of Mus musculus with 4 samples.

How the data were processed

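Tumours of MMTV-PyMT mice with K14-Cre and a tdTomato reporter, on an FVB background, were dissociated enzymatically. Dead cells were removed with magnetic beads, and the cells were profiled on a droplet platform, as 4 libraries from 3 mice. The deposited values are raw UMI counts per gene and cell barcode. FastQC and Cell Ranger 2.2.0 with the mm10 (GRCm38) genome are the tools named per the labels. All values were whole numbers, and the gene table held 55472 entries, a reporter entry among them. The lowest total was 836, 1601, 1389 and 1351 UMIs per barcode in tumours 1 to 4, so the barcodes were already a set of called cells. The median number of genes per barcode was 842, 1321, 1142 and 1079.

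Cells with at least 300 genes and under 15% mitochondrial UMIs were kept. The gene minimum removed 24 barcodes and the mitochondrial limit 0. Scrublet, run per library at its automatic threshold, called 2 doublets among 36162 barcodes, and these were removed. That is far below the rate of about 7% assumed for such loads, so doublet removal did not work and doublets remain among the 36136 cells. Removal of the 8% of cells with the highest scores was tried as an alternative. Counts were scaled to 10000 per cell and log-transformed. Clustering used 2000 variable genes chosen with tumour as batch, plus 108 marker genes of 16 cell types. It used 30 principal components, 15 neighbours and the Leiden method at resolution 1, which gave 21 clusters. Each cluster was named after a type whose markers it held. A type needed at least 3 markers found in at least 10% of the cluster's cells. Of the clusters 14 were luminal epithelial-like and 1 stayed unnamed. Clusters named after other types had markers of that type among their 10 leading genes. The luminal clusters had no luminal marker among theirs, and every cluster met the marker minimum of luminal epithelial-like cells. That minimum alone thus does not set the luminal class apart. Luminal and basal-like cells were clustered again on values scaled within each tumour, at resolution 0.3. The 270 genes of 16 lists were left out of both clusterings. Between classes and sub-clusters only these genes are reported, because genes that shape clusters cannot be tested between them. The tdTomato reporter, described later, is an exception. Comparisons between tumours also used other genes. Marker genes that vary with held-out genes stayed in the clustering. Differences of held-out genes between classes or sub-clusters may therefore in part be set by it, which their p-values do not measure. The lists cover EMT transcription factors, mesenchymal and matrix genes, junction and identity genes, cytokines, interferon response, MHC class I, MHC class II, hypoxia and glycolysis, oxidative phosphorylation, proliferation, milk and alveolar genes, hormone sensing, dissociation and stress, TGF-beta, growth factors, and immune checkpoints. All 270 were found, 2 of them under newer symbols (Ccn1 and Ccn2).

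Cells were not treated as replicates. Raw counts were summed per mouse and class, with both tumours of mouse 3 together, for classes with at least 20 cells in each mouse. They were fitted in edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test) with mouse as a block. Each class was compared with luminal epithelial-like cells, and each epithelial sub-cluster with the mean of the other sub-clusters. P-values were adjusted by Benjamini-Hochberg over 9410 genes for classes and 14270 for sub-clusters, with calls at 0.05. Of the list genes 222 and 233 passed the count filter. Lists were tested with fry in limma 3.58.1, adjusted over the lists of a comparison. The p of fry tests whether the genes of a list move one way on balance, and compares the list with no other genes. An estimated correlation was used in camera as an alternative. Of 96 list tests between classes 73 passed with fry and 15 with camera, and of 64 between sub-clusters 42 and 1. Log2 fold changes come from the fit, while CPM values are means of the mice. The gland comparison used CPM of summed counts with exact conditional binomial intervals at 95%, and list medians against 10000 random lists of matched expression. Intervals cover counting error only.

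Lists, comparisons, tests and alternatives were fixed before the data were examined, apart from those named as later choices. The genes to name were fixed too. They are list genes that passed, changed the same way in 3 of 3 mice and reached 20 CPM in the higher arm. The 12 highest and 12 lowest were taken for fibroblast-like, basal-like and macrophage-like cells and for each sub-cluster, and the 4 highest and 4 lowest for other classes. The leading gene of each list was added whatever its result. Between the glands the rule was the 10 highest and 10 lowest ratios beyond 2-fold at 50 CPM or more. Between tumours it was the 10 list genes with the widest range at 50 CPM or more. The reporter was left out of the planned comparisons.

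The procedure was tested on simulated data with 3 mice per class. Genes set to a 2-fold change were found in 52.2% of cases at the depth of basal-like cells, 58.2% for endothelial-like, 76.1% for fibroblast-like, 77.6% for macrophage-like, 40.3% for mural-like and 52.2% for T cell-like cells. For sub-clusters 0, 1, 3 and 4 it was 98.5%, 97.0%, 97.0% and 64.2%. At most 0.109% of unchanged genes were called. The simulated classes were not made by clustering, so this rate does not cover differences set by the clustering. Of 100 unchanged lists per comparison, between 4 and 12 had an unadjusted fry p under 0.05. The alternatives were size factors (RLE), a DESeq2 1.42.0 test, no count filter, no mouse term, 4 tumours as units and each mouse left out. Doublets kept, a filter at 500 genes and 10% mitochondrial UMIs, lists kept in clustering, and resolutions of 0.5 and 0.6 were also tried. RLE moved the median log2 fold change of all genes by 0.17 in fibroblast-like, 0.13 in macrophage-like, 0.11 in endothelial-like and 0.11 in mural-like cells. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used.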

Results

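Gene expression was measured in single cells from 4 mammary tumour samples of 3 female mice aged 13 to 14 weeks. The mice carried MMTV-PyMT, a transgene that drives mammary carcinomas. They also carried K14-Cre with a Cre-dependent tdTomato reporter. Tumour 1 was pooled from multiple mammary glands of mouse 1, and tumour 2 came from an inguinal gland of mouse 2. Tumours 3 and 4 came from a thoracic and an inguinal gland of mouse 3. All 4 samples are tumours, so no comparison of conditions was possible, and the stated aim was heterogeneity. The 3 mice were the replicates. The libraries held 8724, 9580, 8434 and 9424 cell barcodes with 20281799, 39370565, 29618360 and 31158441 unique molecular identifiers (UMIs), in the order of tumours 1 to 4. The median number of UMIs per barcode was 1922.5, 3281, 2854 and 2589.5.

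Luminal epithelial-like cells made up most of every tumour, and macrophage-like and fibroblast-like cells came next. Luminal epithelial-like cells were 77.4% ± 10.4 (SD, n = 3 mice) of the cells, macrophage-like cells 6.85% ± 2.27 and fibroblast-like cells 4.69% ± 3.04. Endothelial-like cells made up 3.40% ± 1.65, basal-like cells 2.58% ± 2.22, T cell-like cells 1.68% ± 0.734 and mural-like cells 0.955% ± 0.373. A cluster left unnamed made up 2.48% ± 0.515. It met the marker minimum of macrophage-like and of luminal epithelial-like cells, but its leading genes were of another type. Tumour 2 held the highest luminal share, 87.9% (95% Clopper-Pearson interval 87.2 to 88.5), and the lowest basal-like share, 0.324% (0.220 to 0.459, 31 cells). Tumour 3 held the lowest luminal share, 58.8% (57.7 to 59.8), and the highest fibroblast-like share, 10.2% (9.61 to 10.9). In tumour 4, from the same mouse, these shares were 75.4% (74.5 to 76.3) and 5.91% (5.44 to 6.41). The luminal cells of tumour 2 lay largely in other clusters than those of tumours 1, 3 and 4. Clusters 0, 1 and 14 held 60.4% of the luminal cells of tumour 1, clusters 16 and 12 held 58.5% in tumour 2, clusters 0, 10 and 15 held 59.5% in tumour 3, and clusters 15, 0 and 1 held 54.5% in tumour 4. Dead cells had been removed on a magnetic column, without a sort for a cell type. The shares are therefore those of cells that survived dissociation and this step.

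**Figure D1:**
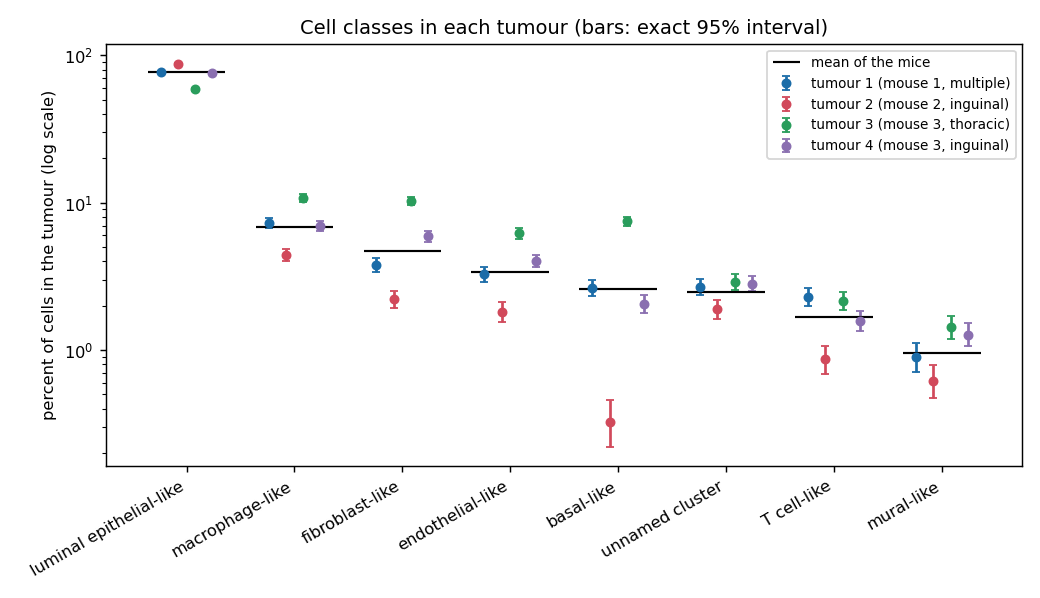
Percent of the cells of each tumour (log scale) in each cell class, with exact 95% intervals as bars and the mean of the 3 mice as a black line. Luminal epithelial-like cells range from 58.8% to 87.9%, and basal-like cells from 0.324% to 7.47%.

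Fibroblast-like cells were compared with luminal epithelial-like cells to describe the stroma against the tumour epithelium. Their genes for matrix, secreted signals and mesenchymal transcription factors were higher, and their milk, junction and respiratory genes were lower. Col6a1, a chain of collagen VI, stood at 818 ± 99.3 CPM (counts scaled to a common library total; SD, n = 3 mice) against 1.24 ± 1.26 in luminal cells. Sparc, which encodes a matrix glycoprotein, stood at 9200 ± 879 against 30.7 ± 16.2 CPM. Of the 21 mesenchymal and matrix genes tested, 20 rose and 1 did not pass, and 20 rose when adjusted over the list alone. The log2 fold change was 9.43 for Col6a1 (ENSMUSG00000001119, GRCm38 chromosome 10, 76708792 to 76726168, minus strand, adjusted p = 1.70e-16), 9.01 for the collagen cross-linking enzyme gene Lox and 8.92 for the fibrillin gene Fbn1. Among 11 EMT (epithelial-mesenchymal transition) transcription factor genes 9 rose and 2 fell, adjusted over the list alone likewise 9 and 2. Twist1 (ENSMUSG00000035799, chromosome 12, 33957671 to 33959829, plus strand) rose by a log2 fold change of 8.34 and Snai1 by 3.10, while Sox9, which is also a gene of epithelial progenitors, changed by -2.29. Of 17 cytokine and chemokine genes 13 rose, 14 adjusted over the list alone, with Cxcl14 at 8.48. Of 13 growth factor genes 7 rose and 2 fell, with the insulin-like growth factor gene Igf1 at 8.23.

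In the same comparison 13 of 14 milk and alveolar genes fell, as they did adjusted over the list alone. Csn1s1 (a casein) changed by -2.83, Wap (whey acidic protein) by -2.72 and Elf5 (the alveolar transcription factor) by -2.55. Junction and identity genes fell in 13 of 15 members, 15 adjusted over the list alone, with Rab25 at -2.42 and Crb3 at -2.28. Oxidative phosphorylation genes fell in 11 of 16 members, 12 adjusted over the list alone, with Ndufa4, a gene of the respiratory chain, at -0.87. Every gene given a direction here changed the same way in 3 of 3 mice. Altogether 167 of 222 list genes passed, 81 higher and 86 lower, and 172 when adjusted over the lists alone. This balance depended on the setting, with 88 higher and 73 lower with size factors in place of TMM, and 82 and 68 in the DESeq2 test. The list tests gave adjusted p = 1.05e-12 for the matrix genes, 1.40e-10 for the EMT factors, 2.97e-10 for the cytokines and 2.27e-08 for the milk genes. With an estimated correlation these lists gave adjusted p = 0.00112, 0.00302, 0.00574 and 0.0209. The junction genes (adjusted p = 1.29e-07), respiratory genes (4.91e-09) and growth factor genes (2.00e-08) did not pass with an estimated correlation, at adjusted p = 0.0511, 0.0511 and 0.0976. Of the fibroblast-like cells, 19.5% held 3 or more UMIs of luminal marker genes. H2-Aa, an MHC class II gene at 8965 CPM in macrophage-like cells, also rose in fibroblast-like cells, by 2.78 in 3 of 3 mice. It stood at 107 ± 24.6 against 15.8 ± 2.90 CPM. Macrophage RNA or doublets may therefore add to the cytokine rise.

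Basal-like cells were compared with luminal cells because both lineages line the mammary duct. Matrix genes and the transcription factor gene Snai2 were higher, and milk and proliferation genes were lower. Snai2 (ENSMUSG00000022676, chromosome 16, 14705852 to 14709385, plus strand) stood at 23.6 ± 6.73 against 0.556 ± 0.318 CPM, a log2 fold change of 5.30 (adjusted p = 3.78e-10, higher in 3 of 3 mice). Of 21 matrix genes 16 rose, 18 adjusted over the list alone, with Sparc at 5.20, Mmp2 (a matrix metalloproteinase) at 5.12, Fbn1 at 3.94 and Vim (vimentin) at 3.24. Dcn, Mgp and Postn, which fibroblasts also express, are among the leading genes of the sub-cluster that holds most of these cells, and H2-Aa rose by 1.47. Doublets with fibroblast-like or macrophage-like cells, or their RNA, may therefore add to the matrix rise. Of 11 EMT transcription factor genes 4 rose and 1 fell, 5 and 1 adjusted over the list alone. Snai1 did not pass, at 0.44 (adjusted p = 0.602). Of 13 growth factor genes 7 rose and 1 fell, 8 and 1 adjusted over the list alone, with the receptor gene Fgfr2 at 3.47. Of 17 cytokine genes 4 rose, the same number adjusted over the list alone, with Cxcl14 at 6.11, Il33 at 3.74 and Cxcl12 at 3.38. Of 14 milk genes 13 fell and 1 rose, also adjusted over the list alone, with Wap at -3.00, Ltf (lactoferrin) at -2.71 and Wfdc18 at -2.42. Of 20 proliferation genes 8 fell, 12 adjusted over the list alone, with Birc5 at -1.37, and Mki67 at -0.68 did not pass (adjusted p = 0.135). The prolactin receptor gene Prlr changed by -1.56, and of 4 hormone-sensing genes 1 rose and 2 fell, 2 and 2 adjusted over the list alone.

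Each basal-like gene named with a direction changed that way in 3 of 3 mice. In this comparison 90 of 222 list genes passed, 48 higher and 42 lower, and 101 adjusted over the lists alone. This balance also depended on the setting, with 51 and 35 with size factors, 52 and 30 in the DESeq2 test, and 51 and 63 without the count filter. Adjusted p of the list test was 5.17e-06 for both the matrix and the milk genes, 2.01e-05 for proliferation, 5.13e-05 for growth factors and 0.000102 for the EMT factors. With an estimated correlation these 5 lists gave adjusted p = 0.00543 for matrix and for milk genes, 0.0304 for proliferation, 0.0196 for growth factors and 0.0304 for the EMT factors. The cytokine list (adjusted p = 0.000546) did not pass with an estimated correlation, at adjusted p = 0.0980. The hormone-sensing list had no direction (adjusted p = 0.257). Without mouse 3, which supplied 823 of the 1085 basal-like cells, 47 genes passed, and without mouse 1 the number of lists with a direction went from 10 to 6. The class held only 31 cells in mouse 2.

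Macrophage-like cells carried high levels of antigen presentation, chemokine and checkpoint genes. Cd74, the invariant chain of MHC class II, stood at 23372 ± 7768 against 41.7 ± 6.38 CPM in luminal cells, and H2-Aa, a class II chain, at 8965 ± 2356 against 15.8 ± 2.90 CPM. All 7 MHC class II genes rose, as they did adjusted over the list alone, with log2 fold changes of 9.18 for H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823, minus strand, adjusted p = 4.01e-17) and 9.14 for Cd74. All 7 immune checkpoint genes rose, on both adjustments, among them Havcr2 (the gene of TIM-3) at 9.14 and the co-stimulatory ligand gene Cd86 at 8.46. Of 17 cytokine genes 13 rose, also adjusted over the list alone, with Ccl4 at 8.78, Ccl3 at 8.69, Il1b at 8.15 and Cxcl1 at 2.35. Of 11 MHC class I genes 9 rose, as they did adjusted over the list alone, with B2m at 3.07. Of 14 interferon response genes 6 rose and 2 fell, the same adjusted over the list alone, while Isg15 at 0.36 did not pass (adjusted p = 0.118). All 14 milk genes fell, also adjusted over the list alone, with Csn1s2a at -4.82, Csn3 at -3.12 and Elf5 at -2.88. Of 15 junction and identity genes 14 fell, likewise adjusted over the list alone, with Rab25 at -2.95 and Tjp1 at -2.52. Of 21 hypoxia and glycolysis genes 10 rose and 7 fell, 11 and 7 adjusted over the list alone, and the glucose transporter gene Slc2a1 at -0.09 did not pass.

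Each macrophage-like gene named with a direction changed that way in 3 of 3 mice. Here 162 of 222 list genes passed, 95 higher and 67 lower, and 163 adjusted over the lists alone. The list tests gave adjusted p = 2.17e-11 for checkpoint genes and for cytokines, 7.16e-10 for MHC class II and 1.19e-09 for milk genes. With an estimated correlation these lists gave adjusted p = 0.000952, 0.00278, 0.0129 and 0.0129. MHC class I (adjusted p = 5.19e-09), junction (3.08e-07), interferon (0.00112) and hypoxia genes (0.00127) did not pass with an estimated correlation, at adjusted p = 0.130, 0.149, 0.970 and 0.970. Of 17 TGF-beta pathway genes 6 rose and 8 fell, the same adjusted over the list alone, with Tgfb1 at 3.00 and Tgfb2 at -3.28. That list's test pointed up (adjusted p = 0.00442, and 0.970 with an estimated correlation) while its median was -0.37. The respiratory list likewise tested up (adjusted p = 0.0461) with a median of -0.01, 4 members higher and 3 lower on both adjustments. With an estimated correlation the respiratory list pointed down, at adjusted p = 0.970. Of the macrophage-like cells, 9.81% held 3 or more luminal marker UMIs.

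**Figure D2:**
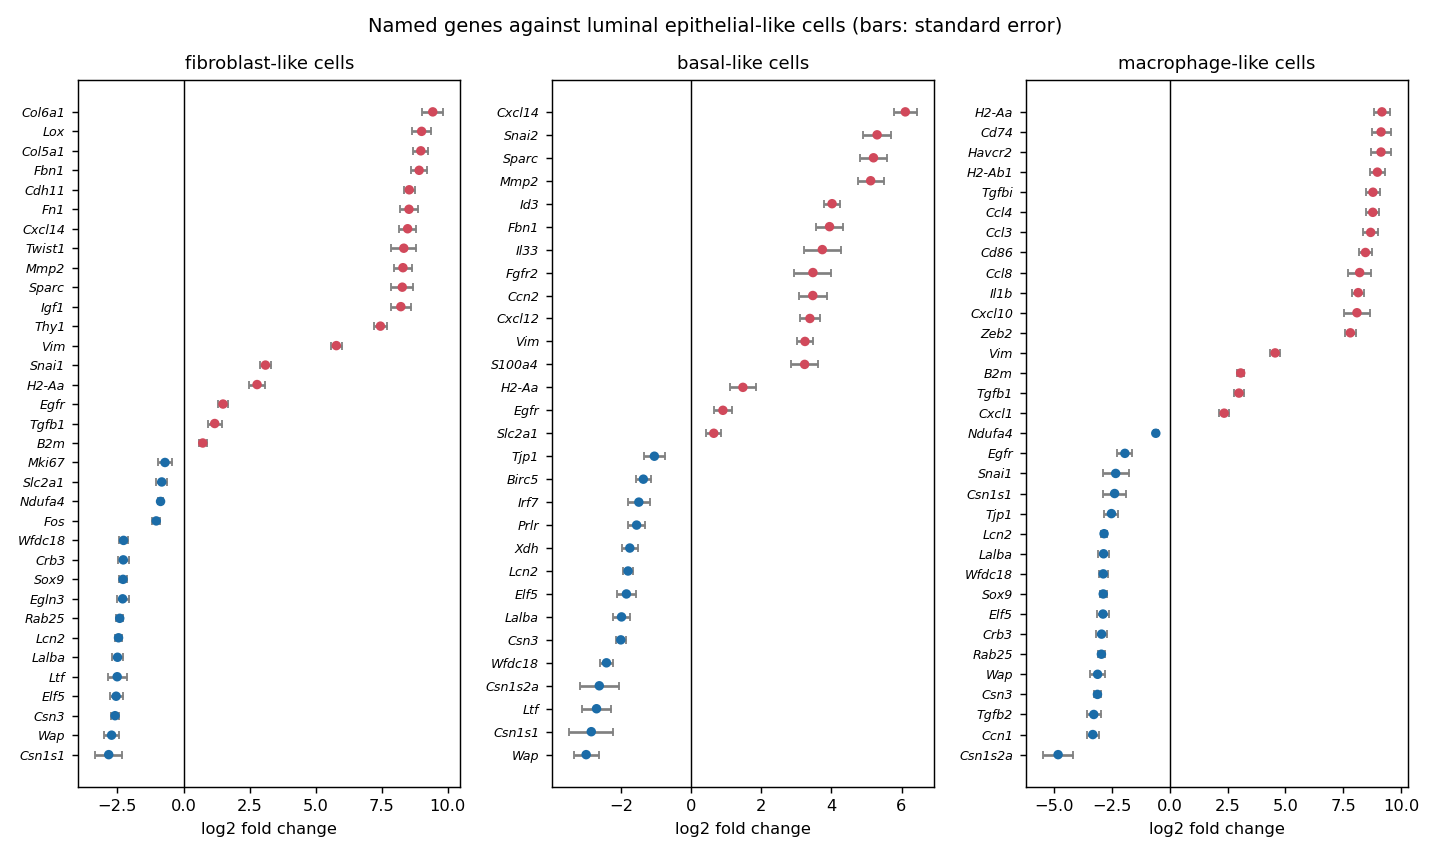
Log2 fold change of the named genes that passed in fibroblast-like, basal-like and macrophage-like cells against luminal epithelial-like cells, with the standard error of the fit (3 mice) as bars. Col6a1 at 9.43 is the highest gene of the fibroblast-like panel and Cxcl14 at 6.11 that of the basal-like panel; H2-Aa at 9.18 leads the macrophage-like panel.

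Endothelial-like, mural-like and T cell-like cells were compared with luminal cells in the same way. In endothelial-like cells the integrin gene Itga5 rose by a log2 fold change of 7.45, the chemokine gene Cxcl10 by 7.14 and the transcription factor gene Zeb1 by 7.07. Matrix genes rose in 14 of 21 members, 15 adjusted over the list alone (adjusted p = 1.24e-06, and 0.184 with an estimated correlation). Tjp1, a tight junction gene, rose by 1.58 there, although 11 of 15 junction genes fell and 2 rose, the same adjusted over the list alone (adjusted p = 1.28e-05, and 0.236 with an estimated correlation). In mural-like cells Thy1 rose by 7.68, Zeb2 by 7.61 and Il34, a ligand of the CSF1 receptor, by 7.49. Matrix genes rose in 18 of 21 members, 20 adjusted over the list alone (adjusted p = 9.36e-09, and 0.000311 with an estimated correlation). EMT factors rose in 7 of 11 members and fell in 1, 8 and 1 adjusted over the list alone (adjusted p = 9.36e-09, and 0.000702 with an estimated correlation). In T cell-like cells Thy1 rose by 7.41, the chemokine gene Ccl5 by 6.75, S100a4 by 6.62 and Tgfb1 by 3.40. Genes of the mesenchymal and matrix list rose there in 6 of 21 members and fell in 1, 8 and 1 adjusted over the list alone (adjusted p = 0.000350, and 0.266 with an estimated correlation). Thy1 and S100a4 are among the members that rose, so the rise need not concern matrix genes. MHC class I genes rose there in 6 of 11 members, also adjusted over the list alone (adjusted p = 3.93e-06, and 0.0797 with an estimated correlation). Proliferation genes rose in 7 of 20, 8 adjusted over the list alone (adjusted p = 0.000430, and 0.345 with an estimated correlation). Each gene named here with a direction changed that way in 3 of 3 mice.

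Of 222 list genes, 65 were higher and 60 lower in endothelial-like cells (127 in all adjusted over the lists alone), 53 and 37 in mural-like cells (102) and 48 and 32 in T cell-like cells (86). Milk genes fell in 12 of 14 members in endothelial-like, 10 in mural-like and 12 in T cell-like cells, 13, 11 and 13 adjusted over the list alone. Their adjusted p was 1.62e-06, 7.95e-05 and 4.83e-05, and with an estimated correlation adjusted p = 0.148, 0.0560 and 0.0797. Of the endothelial-like cells 31.3% held 3 or more luminal marker UMIs, of the mural-like cells 46.6% and of the T cell-like cells 42.7%. Without mouse 3, 54 genes passed in mural-like cells and 42 in T cell-like cells, and without the mouse term 46 passed in T cell-like cells. With size factors in place of TMM the mural-like split was 56 higher and 25 lower, and without the count filter the endothelial-like split turned to 68 higher and 77 lower.

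Within the epithelium, sub-cluster 3 carried the proliferation genes. This sub-cluster was 13.2% ± 1.5 (SD, n = 3 mice) of the epithelial cells. All 26 proliferation genes tested were higher there than in the mean of the other sub-clusters, also adjusted over the list alone. Tpx2, a spindle assembly gene (ENSMUSG00000027469, chromosome 2, 152847964 to 152895321, plus strand), stood at 84.3 ± 16.8 against 2.92 ± 1.97 CPM, a log2 fold change of 4.66 (adjusted p = 3.60e-17, 3 of 3 mice). Among the others, Ube2c rose by 4.38, Top2a by 3.95 and Mki67 by 3.28. Other cell cycle genes such as Pclaf, Cenpa and Hmmr were not held out of the clustering, so this rise may in part be set by it. Of 16 oxidative phosphorylation genes 11 rose and 1 fell, 12 and 1 adjusted over the list alone. Of 15 dissociation and stress genes 13 fell, also adjusted over the list alone, with the immediate early gene Fos at -0.71. Of 15 matrix genes 14 fell, likewise adjusted over the list alone, with Sparc at -2.31 and Ccn2 at -2.28. The mean of the others includes the basal-like sub-cluster 4, where Sparc stood at 962 CPM, against 20.5 in sub-cluster 3 and 27.0 in sub-cluster 0, so this fall may largely restate its presence. Of 12 MHC class I genes 7 fell and 1 rose, 7 and 2 adjusted over the list alone, with B2m at -0.75. In all 158 of 233 list genes passed, 47 higher and 111 lower, and 170 adjusted over the lists alone. The list tests gave adjusted p = 0.000163 for proliferation and for matrix genes, 0.000512 for respiratory, 0.000695 for stress and 0.00225 for MHC class I genes. None of these passed with an estimated correlation, at adjusted p = 0.0567, 0.0567, 0.242, 0.143 and 0.177. Without the mouse term 73 genes passed, 33 higher and 40 lower. Without mouse 3 the split was 46 higher and 64 lower, so the tilt to lower genes depended on the setting. Cells of this sub-cluster had a median of 4450 UMIs, against 2703.5 and 2693 in sub-clusters 0 and 1.

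Sub-cluster 1, 47.4% ± 4.24 of epithelial cells in this clustering, had higher milk, stress and interferon genes and lower proliferation genes. All 14 milk genes rose, on both adjustments, with Ltf at 247 ± 66.6 against 43.6 ± 17.8 CPM (log2 fold change 2.50, adjusted p = 2.02e-10, 3 of 3 mice), Btn1a1 at 2.27 and Wfdc18 at 2.04. Csn1s1 rose by 1.49, with 2 of 3 mice higher. Of 15 interferon response genes 12 rose, also adjusted over the list alone, with the interferon regulatory factor gene Irf7 at 2.11, Ifit1 at 1.93 and Isg15 at 1.44. All 15 dissociation and stress genes rose, likewise adjusted over the list alone, with Fos at 0.85. The enzymatic dissociation of the tissue may add to this rise, which was not tested. Of 22 hypoxia and glycolysis genes 12 rose and 3 fell, 13 and 4 adjusted over the list alone, with Ndrg1 at 1.36. All 26 proliferation genes fell, also adjusted over the list alone, with Ccnb1 at -2.89, Birc5 at -2.88 and Mki67 at -1.97. Mki67 stood at 4.24 ± 0.337 against 26.3 ± 1.11 CPM (SD, n = 3 mice). With log CPM averaged over the other sub-clusters, as in the counts of mice, 2 of 3 mice were lower. The mean of the others includes sub-cluster 3, and in sub-cluster 0 proliferation genes also fell, in 18 of 26 members, 19 adjusted over the list alone (adjusted p = 0.0222, and 0.0899 with an estimated correlation). Sub-cluster 0, 35.7% ± 3.20 of epithelial cells, had higher Wap (1.60, 3 of 3 mice) and Lalba (0.99), the gene of alpha-lactalbumin. Its milk genes rose in 8 of 14 members and fell in 1, 8 and 2 adjusted over the list alone. Matrix genes fell in 10 of 15, 11 adjusted over the list alone, with Sparc at -1.75. Growth factor genes fell in 8 of 16 and rose in 2, also adjusted over the list alone, with Pdgfa at -1.14. Both falls are against a mean that includes the basal-like sub-cluster 4, where Sparc stood at 962 and Pdgfa at 89.3 CPM, and may largely restate its presence. Wap stood at 14.2 CPM there, so the milk rises of sub-clusters 0 and 1 are also larger for its part in the mean.

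In sub-cluster 1, 158 of 233 list genes passed, 107 higher and 51 lower, and 167 adjusted over the lists alone. Adjusted p was 0.000555 for milk, stress and hypoxia genes, 0.00106 for interferon and 0.00584 for proliferation genes. None of these passed with an estimated correlation, at adjusted p = 0.0869 for milk and stress genes, 0.108 for hypoxia, and 0.104 for interferon and proliferation genes. In sub-cluster 0, 83 passed, 19 higher and 64 lower, and 100 adjusted over the lists alone. Its matrix genes gave adjusted p = 4.47e-05, and 0.00272 with an estimated correlation, with sub-cluster 4, whose matrix genes had a median log2 fold change of 3.29, in the reference. Its milk (0.0222) and growth factor genes (0.00613) did not pass with an estimated correlation, at adjusted p = 0.0899 and 0.0750. The borders of these sub-clusters moved with the clustering. With another seed the overlap with the matching sub-cluster, as shared cells over all cells of both, was 0.526 for sub-cluster 0 and 0.411 for sub-cluster 1. The match of sub-cluster 1 then held 6110 cells, against 13399 here, and that of sub-cluster 0 held 16854 against 10118, so their order by size turned. Without the mouse term 10 genes passed in sub-cluster 0 and 74 in sub-cluster 1. Without mouse 3, 44 passed in sub-cluster 0, and in sub-cluster 1 the split was 80 higher and 31 lower. The number of lists with a direction in sub-cluster 0 went from 6 to 1 without mouse 1, and to 1 without mouse 3.

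Sub-cluster 4 was made up mostly of basal-like cells, 969 of its 1019, and its genes are close to a repeat of the basal-like comparison. It was 3.39% ± 2.87 of the epithelial cells, with 0.473% in tumour 2 and 9.87% in tumour 3. Matrix genes rose in 14 of 15 members, also adjusted over the list alone, with Sparc at 962 ± 187 against 28.4 ± 16.4 CPM (log2 fold change 5.21, adjusted p = 1.55e-14, 3 of 3 mice) and Mmp2 at 5.02. Fibroblast RNA or doublets may add to this rise here too. Milk genes fell in 12 of 14 and rose in 1, the same adjusted over the list alone, with Wap at -3.11. Junction genes fell in 10 of 20 and rose in 3, also adjusted over the list alone, with Rab25 at -1.32. In all 102 of 233 list genes passed, 54 higher and 48 lower (56 and 62 without the count filter), and 112 adjusted over the lists alone. Adjusted p was 0.00431 for matrix and for milk genes and 0.0293 for junction genes. None passed with an estimated correlation, at adjusted p = 0.0739, 0.0739 and 0.364. Without mouse 3, 62 genes and 2 lists passed, without mouse 1 the lists went from 10 to 0, and without the mouse term 64 genes passed. A further sub-cluster of 59 cells was too small to test.

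The thoracic and inguinal tumours of mouse 3 were compared in luminal epithelial-like cells to see how far 2 glands of a single animal differ. They were alike in most genes. Of 2278 genes at 50 CPM or more, 4 were over 2-fold higher in the thoracic and 6 in the inguinal tumour, with a 95% counting interval beyond 2-fold. Higher in the thoracic tumour were Amtn, the gene of amelotin (67.3 against 10.1 CPM, ratio 6.65, interval 5.80 to 7.64), and Npy, the gene of neuropeptide Y (ratio 4.15, 3.70 to 4.66). Car6, a secreted carbonic anhydrase gene (3.46, 3.34 to 3.58), and Lgals7 (2.26, 2.21 to 2.32) followed. Higher in the inguinal tumour were the retinol-binding protein gene Rbp7 (5.24-fold, 4.51 to 6.12), Cd27 (2.81, 2.52 to 3.14), Tspan8 (2.30, 2.15 to 2.46), Fcgbp (78.8 against 35.7 CPM, interval of the ratio 2.02 to 2.41) and the casein gene Csn3 (2.06, 2.04 to 2.08). The immunoglobulin light chain gene Igkc was 138-fold higher in the inguinal tumour (75.0 to 289), with 1719 of its 1743 UMIs in 1 cell. All 5 proliferation genes at this level were higher in the thoracic tumour, with a median log2 ratio of 0.62, at percentile 99.99 of 10000 random lists of matched expression. All 3 interferon response genes were lower there (median -0.82, percentile 0), as were 9 of 10 milk genes (median -0.31, percentile 0). Of 13 dissociation and stress genes 11 were lower (median -0.30, percentile 0.01). The random lists were drawn gene by gene and so lack the shared movement of genes in such lists. Extreme percentiles are therefore easier to reach, and they are no test of the glands. Sub-cluster 3 was 14.2% of the epithelial cells in the thoracic and 10.5% in the inguinal tumour, and sub-cluster 1 39.8% and 49.3%. These shares go the same way as the 4 lists and were not separated from them. With 1 tumour per gland no test was possible, and the intervals cover counting error only.

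Between all 4 tumours, the luminal genes with the widest ranges belonged to the milk, interferon, glycolysis and matrix lists. The interferon genes were highest in tumour 2. Irf7 stood at 151 CPM there against 27.6, 32.0 and 46.3 in tumours 1, 3 and 4, Ifitm3 at 1450 against 696, 290 and 583, and Isg15 at 194 against 65.7, 45.4 and 80.7. The glycolytic enzyme genes Aldoa (2633 against 761, 865 and 857 CPM) and Ldha (2065 against 677, 774 and 1013) were also highest in tumour 2. Milk genes did not move together. Csn1s2a was highest in tumour 1 (75.7 against 8.67, 18.5 and 12.5 CPM), Csn3 in tumour 2 (9091 against 3331, 2626 and 5410), Mfge8 in tumour 4 (618 against 467, 185 and 565) and Csn1s1 in tumour 1 (53.0 against 22.7, 16.6 and 48.9). Sparc ranged from 15.4 CPM in tumour 2 to 57.1 in tumour 3, the tumours with the lowest and highest shares of fibroblast-like and basal-like cells. Sparc is abundant in fibroblast-like cells, so their RNA among luminal cells may account for this range. Over 2522 genes, 22 differed by more than 2-fold between the tumours of mouse 3. Between mice the number was 205 for tumours 1 and 2, 123 for 2 and 3, 95 for 1 and 3, 95 for 1 and 4, and 90 for 2 and 4. Each mouse other than mouse 3 gave a single sample, so these values carry no test.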

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

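The tests that set macrophage-like cells as the comparison, the K14-Cre lineage test, the salivary test without Aqp5 and the test of the top 2 Igkc cells were chosen only after the results were seen. So was the test against luminal cells. The measures of single genes had been picked for wide ranges. Of 41 measures over the 4 tumours, 5 had a tumour far from the others, and chance gives about 1 in 20. Tumours 3 and 4 share a mouse.

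In luminal epithelial-like cells Csn1s2a stood at 75.7 CPM in tumour 1, where the next tumour had 18.5. Tumour 2 stood apart with 151 CPM of Irf7, 2633 CPM of Aldoa and 306 CPM of Rbp7, where the next tumours had 46.3, 865 and 52.8. Fcgbp stood at 78.8 CPM in tumour 4, with 41.1 in the next. The unnamed cluster held 924 cells that no comparison used. Its leading genes included S100a8, Ccl6 and H2-Aa, and 66.7% of its cells held 3 or more luminal marker UMIs. Without the highest doublet scores an unnamed cluster, also with these 3 genes among its leading ones, held 279 cells. Macrophage-like cells then went only from 2620 to 2590. Doublets are therefore a candidate for part of the unnamed cluster, which was not tested.

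The tdTomato reporter, which no planned comparison used, gave 217071 UMIs in all, and fibroblast-like cells held 5.33 ± 1.01 per 10000 UMIs (SD, n = 3 mice). Were this epithelial RNA in the same droplets, its ratio to luminal marker UMIs would match that of luminal cells, but it was higher in 4 of 4 tumours (0.776, 0.427, 0.711 and 0.689 against 0.583, 0.390, 0.632 and 0.622). After that result the comparison was changed to macrophage-like cells, where the ratio was higher still (0.867, 0.469, 0.771 and 0.746), so that the median quotient was 0.917. T cell-like, mural-like and endothelial-like cells held more tdTomato, at 11.1, 10.2 and 8.60 per 10000 UMIs. Their mean ratios were 0.530, 0.532 and 0.612, against 0.533 in luminal and 0.866 in basal-like cells. With RNA from basal-like cells the ratio need not match that of luminal cells. The comparisons with luminal and macrophage-like cells point different ways, and RNA from epithelial cells stays open. Fibroblast-like cells of the K14-Cre lineage would carry more tdTomato than macrophage-like cells when no luminal marker UMI is present. Fibroblast-like cells carried less in each tumour (median quotient 0.812). Endothelial-like, T cell-like and mural-like cells without such a UMI held 2.54 ± 0.507, 2.12 ± 1.25 and 2.05 ± 0.865 per 10000 UMIs. Macrophage-like cells held 1.48 ± 0.332, so the background may differ between classes. The result argues only against this lineage in the class as a whole, since a mean cannot exclude a few such cells.

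Luminal cluster 14 held 973 cells, 841 of them (86.4%) from tumour 1, the sample pooled from multiple glands, and was led by Scgb1b27, Smr2, Mup4 and Car6. At resolution 0.5 a cluster led by Scgb1b27, without Smr2, Mup4 or Prol1 among its leading genes, held 1690, 68, 512 and 933 cells of tumours 1 to 4. Sub-clustering of those luminal and basal-like cells gave 1435 cells led by Scgb1b27, 638 of them from tumour 2. Its values were scaled within each tumour, which favours such a spread. At resolution 1 tumour 1 gave 828 of 968 such cells without the highest doublet scores and 956 of 1125 with the stricter filter. It gave 1431 of 1752 with lists kept in clustering and 1546 of 2198 with another seed. How far such cells were confined to tumour 1 thus depended on the clustering. Of 8 salivary transcripts, tested for salivary tissue collected with the glands, the highest was Aqp5, in 63.3% of these cells and 39.0% of other luminal cells of tumour 1 (median 2277 and 2092 UMIs), which left the test undecided, as Aqp5 is not specific. The highest share of the other 7 was 0.119%, which argues only against cells that carry those, and the median doublet score was 0.860 times that of other luminal cells, which argues against doublets, although few were called at all. Smr2 (30.2% against 2.48% of cells), Prol1 (30.1% against 3.21%) and Car6 (66.8% against 25.5%) are also secretory transcripts of salivary or lacrimal glands, so cells of another gland stay open, as does an untested difference between mouse 1 and the other mice.

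Igkc stood at 248 and 70.3 CPM in luminal cells of tumours 1 and 4, against 0.422 and 0.508 in tumours 2 and 3, but 2 T cell-like cells of tumour 2 held 1436 Igkc UMIs, so the gap to tumour 2 lies in the class of such cells. The planned test, of the share held by the 1% of cells with most UMIs, gave 100% but was void, since under 1% of the cells had any UMI in each tumour. The top 2 cells held at least 98.1% in both tumours, and single cells also held up to 352 UMIs of Igha and 221 of Jchain, so a few plasma cells counted as luminal are a candidate source. No cell of any tumour held more than 1 UMI of the plasma cell gene Mzb1 or 8 of Derl3. Mzb1 had 1 UMI in tumour 4 and 0 in the others, and Derl3 had 326 and 404 luminal UMIs in tumours 1 and 4. Neither gene therefore decides this. Free plasma cell RNA would give like levels in all classes, but they differed by up to 44.1-fold, a gap that rests on the same 2 cells, so it argues against free RNA for the excess and leaves the remaining UMIs open. No biological difference between the tumours was tested.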

How the results depend on the processing

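The removal of the cells with the highest doublet scores, of cells with 3 or more luminal marker UMIs and the other clustering seed were chosen after seeing the data. The named genes of the class comparisons gave 2630 values over the alternatives, of which 2545 stayed on their side of the threshold, 63 no longer passed, 22 newly passed and 0 changed sign. In the sub-clusters, 1745 of 1922 values stayed, 150 no longer passed, 12 newly passed and 15 changed sign. For tdTomato, 138 of 141 values stayed, 1 no longer passed and 2 newly passed. A change of sign was counted only where a value passed before or after. Others that passed in neither also turned, such as tdTomato in sub-cluster 0, at -0.05 without the highest doublet scores. The number of genes over 2-fold between the glands, 10, went from 9 to 13. The count of called genes lay between 91 and 145 over all alternatives for endothelial-like, 129 and 199 for fibroblast-like and 133 and 176 for macrophage-like cells.

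Without the mouse term, 46 genes passed in T cell-like cells, and 10, 74, 73 and 64 in sub-clusters 0, 1, 3 and 4, since differences between mice then add to the spread. Leaving out a mouse in turn gave 47 to 90 genes in basal-like, 54 to 82 in mural-like and 42 to 76 in T cell-like cells, and 44 to 78 in sub-cluster 0 and 62 to 103 in sub-cluster 4. The lowest of each came without mouse 3. The lists with a direction went to 6 to 9 in basal-like cells, 1 to 4 in sub-cluster 0 and 0 to 9 in sub-cluster 4. With an estimated correlation the lists that passed went to 5 in basal-like, 0 in endothelial-like, 4 in fibroblast-like, 4 in macrophage-like, 2 in mural-like and 0 in T cell-like cells, from 10, 13, 14, 15, 12 and 9. In sub-clusters 0, 1, 3 and 4 they went to 1, 0, 0 and 0, from 6, 13, 13 and 10. The respiratory list of macrophage-like cells turned down there, with adjusted p = 0.970. Camera compares a list with other genes, which fry does not.

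The stricter cell filter gave 97 genes in sub-cluster 1, and resolution 0.6 gave 81. Removing the highest doublet scores gave 45 genes in sub-cluster 0 and a share of the unnamed cluster of 0.763%. The cause was not tested for these 4 values, nor for the changes of sign that follow. At resolution 0.5 the macrophage-like share was 9.16%. No cluster stayed unnamed there, and the macrophage-like cluster held 3474 cells, against 2620 macrophage-like and 924 unnamed cells at resolution 1. In sub-cluster 0, Wfdc18 went to -0.30 without the highest doublet scores. H2-Aa, which had not passed there, went to -1.56 with called doublets kept, -1.45 with lists kept in clustering, -1.34 without the highest doublet scores and -0.87 with another seed. Csn1s1 there went to -1.62 with another seed, and Mki67 ranged from -0.88 to 0.25 as each mouse was left out, the highest without mouse 3. In sub-cluster 1, Csn2 went to -0.79 with called doublets kept and -0.026 with the stricter filter, and Slc2a1 to -0.032 with that filter. In sub-cluster 4, H2-Aa went to -0.64 with called doublets kept, -0.75 with the stricter filter, -0.49 with lists kept in clustering and -0.25 without the highest doublet scores. Csn1s1 there went to 1.28 with another seed. Sub-clusters without a match could join the mean of the others. With called doublets kept, lists kept in clustering, the highest doublet scores removed or the stricter filter, such a sub-cluster was led by Cd74. It held 153, 199, 290 and 333 cells in that order, with H2-Aa among its leading genes. The negative H2-Aa values there cannot be separated from this change of reference. With another seed no sub-cluster was led by Cd74. The stricter filter gave no match, and so no value, for sub-cluster 0. Depth limits the smaller classes, where simulated 2-fold changes were found in 40.3% of cases for mural-like and 52.2% for basal-like cells.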

Other observations

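The tdTomato values and the sub-clusters at resolution 0.6 described here were chosen for description after the data were seen. The reporter was highest in luminal epithelial-like cells, at 20.2 ± 2.43 UMIs per 10000 (SD, n = 3 mice), and stood at 14.1 ± 3.27 in basal-like, 5.33 ± 1.01 in fibroblast-like and 3.07 ± 0.320 in macrophage-like cells. It fell in all 6 classes compared with luminal cells in 3 of 3 mice, with log2 fold changes of -0.66 in basal-like (adjusted p = 0.00120), -1.43 in endothelial-like, -2.01 in fibroblast-like, -2.44 in macrophage-like (adjusted p = 2.30e-13), -1.13 in mural-like and -0.81 in T cell-like cells. In cells without a luminal marker UMI it stayed at 17.4 ± 2.60 in luminal and 11.8 ± 3.65 in basal-like cells, and stood at 1.2 ± 0.338 in fibroblast-like and 1.48 ± 0.332 in macrophage-like cells. The luminal and basal-like values rest on only 130 and 244 cells, with as few as 3 and 1 in a tumour. Within the epithelium it was higher in sub-cluster 1 (0.94, adjusted p = 2.73e-08) and lower in sub-clusters 3 (-0.59) and 4 (-0.53), each in 3 of 3 mice, and did not pass in sub-cluster 0 (0.19, adjusted p = 0.169). Over the alternatives the change lay between -0.83 and -0.45 in basal-like, -2.88 and -1.29 in endothelial-like, -3.81 and -1.84 in fibroblast-like, -3.30 and -1.34 in macrophage-like, -2.98 and -0.97 in mural-like and -2.78 and -0.74 in T cell-like cells. It lay between -0.05 and 0.36 in sub-cluster 0, 0.68 and 0.95 in sub-cluster 1, -0.76 and -0.43 in sub-cluster 3 and -0.63 and -0.36 in sub-cluster 4.

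At the finer resolution 639 epithelial cells from all 4 tumours, 263 of them from tumour 3, formed a sub-cluster with higher interferon genes. Of 14 interferon response genes 13 rose there against the mean of the other sub-clusters, with log2 fold changes of 6.96 for Rsad2, 6.43 for Ifit3, 5.23 for Ifit1 and 4.06 for Isg15, each in 3 of 3 mice. Rsad2 stood at 209 ± 154 against 2.01 ± 1.72 CPM. Of 11 MHC class I genes 9 rose, and of 26 proliferation genes 6 fell. These lists had been kept out of the clustering genes, but other interferon genes had not, so the sub-cluster is in part defined by this response. Its leading genes also include Col27a1, Smim5, Spaar and S100b, which are not interferon genes. With another seed, 320 of these cells fell in the matching sub-cluster of 395 cells, 45 of them from tumour 3. At resolution 0.3 with that seed, 200 cells led by Col27a1, 167 of them from tumour 3, formed a sub-cluster of their own. The 639 cells may therefore hold a second group, and how many carry the interferon response was not counted.

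To test whether the counts of called genes need the real classes, class labels were shuffled within mice 2 and 3. That gave 25 labellings with the real one, a number set for running time before any outcome was seen. In each of the 10 comparisons 1 of the 25, the real one, called as many genes. The classes were made by clustering the expression of these same cells, so a lead over shuffled labels was largely set beforehand and decides nothing on chance. The real counts were 90, 125, 167, 162, 90 and 80 in basal-like, endothelial-like, fibroblast-like, macrophage-like, mural-like and T cell-like cells, and the highest of the others 0, 0, 6, 62, 0 and 0. For sub-clusters 0, 1, 3 and 4 the real counts were 83, 158, 158 and 102 and the highest others 1, 27, 38 and 49.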
